A study of Cyprinus carpio with 93 samples.

How the data were processed

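Total RNA of common carp tissues kept in RNAlater was sequenced by the submitters after standard Illumina library preparation, as the labels state. The authors aligned reads with TopHat2 2.0.5 and deposited 1 table per library of counts per gene model, in the layout that HTSeq-count writes; the counting tool is not named. The values are raw counts of whole reads, with 5 summary lines that were set apart, 3 of them 0 in every library. The authors also deposited gene models as GFF positions (start, end, strand, product and symbol) of MAKER gene models on contigs of a carp assembly that is not named, so positions are on those contigs and no chromosome can be given. The reference gene table at hand uses other identifiers and was not used. Of 50527 gene models, 45320 (89.7%) carry a symbol, in 14751 distinct symbols ignoring case. Reads outside gene models made up 21.6% to 82.3% of reads per library (median 37.6%), and ambiguous reads at most 0.0742%.

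All 93 libraries were used. Totals of 233640 to 11119063 counts in gene models set the floor of detection, taken as 3 counts over a group. A fold against a group with no count is given as at least the other group's CPM over that floor, and a group with 1 to 3 counts gets a ratio with its 95% counting interval. Shares of counts in single libraries carry exact Clopper-Pearson 95% intervals from scipy 1.17.1. No 2 libraries of the same group were alike to within sampling noise; pairs across groups were not tested for it.

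Differences were tested in R 4.3.3 with edgeR 4.0.16 by TMM normalization, filterByExpr, trended dispersion and the quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Muscle, skin, kidney, tectum with torus and larvae were each fitted alone. The eye parts shared a fit of 6 libraries, and the paired fins a fit with the other fins and tail. Left and right were tested within 15 pairs as blocks, without mid kidney, whose titles give both sides. Each tissue with at least 2 libraries was tested against the other 18 tissues over 89 libraries, larvae left out. The contrast was with the unweighted mean of the fitted log2 levels of the other tissues, and asked for a log2 fold of at least 2. The difference between muscle and skin in the dorsal to ventral fold was an interaction term. For 33 gene lists (cell types, tissues and pathways), camera of limma 3.58.1 compared list members with all other genes on log2 CPM (prior count 2, preset correlation 0.01, adjusted over the lists of a comparison), and again with an estimated correlation. A symbol matched a list ignoring case, and every model with the symbol was a member.

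Named genes followed a rule. In pairwise comparisons they had an adjusted p under 0.05, a symbol, a mean of at least 5 CPM in the higher group and CPM that did not overlap between the groups (left and right: the same sign in at least 12 of 15 pairs), with the 10 largest log2 folds in each direction, 1 model per symbol, plus list members. In tissues they were enriched genes with a symbol and at least 10 CPM, the 4 with the largest ratio to the highest other tissue (0.1 CPM added to both), plus list members. For single libraries they were list members or the 4 genes of at least 50 CPM with the largest ratio to the highest other tissue or brain region, given as values with no test.

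The alternatives were DESeq2 1.42.0 (Wald test, its own size factors), RLE factors, no filter on low counts, a log2 fold of at least 1, 5 times the highest other tissue, a fit to all 93 libraries, fits to the compared libraries only, the shared letters, numbers or sides as a replicate block, and each library left out in turn. The labels do not say that shared letters, numbers or sides mark the same animal. No comparison with 3 or more pairs had every pair's correlation over 0.1, so the block stayed an alternative. The correlation was over 0.1 in larvae, tectum and torus, eye front and rear and the fins. These comparisons have only 2 pairs each, which give the same r by construction when each group holds 2 libraries. There the block called more genes than the main fit. A fit without the hepatopancreas, spleen and optical nerve libraries was added after seeing the data. Regroupings of the same samples were drawn at random, 100 for muscle, skin and dominance, all 35 for kidney, 60 for left and right, and 24 for tissues on a sample of 10000 genes; the last numbers were reduced to save computing time after a longer run had been seen. The tests were checked on simulated data with 200 changed genes. Extreme libraries were sought with Dixon's test in groups of 4 to 10 libraries. Python 3.11 and matplotlib 3.10.9 were used for tables and plots. Nothing was left out other than the summary lines and, where stated, the larvae and mid kidney.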

Results

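RNA sequencing of total RNA covered 93 libraries of common carp tissues, in 38 groups set by the titles and 20 tissue labels. The largest groups were gill with 6 libraries, and dorsal muscle, ventral muscle, dorsal skin, ventral skin, gallbladder and hepatopancreas with 5 each. Head kidney, mid kidney, spleen and thymus had 4 libraries each. Barb (a sensory whisker of the mouth), brain body, crystalline (the eye lens), eye front, eye rear, pectoral fin, pelvic fin, dorsal fin, tail, tectum opticum, torus semicircularis, male gonads, larvae labelled control and larvae labelled infected had 2 each. Atrium, ventricle, bulbus, anal fin, gut, swim bladder, PBL (tissue label blood), pituitary, telencephalon, corpus cerebelli, medulla oblongata, vagal lobe and optical nerve had 1 library each and therefore no replicate. The total count in gene models ran from 233640 in the optical nerve to 11119063 in dorsal skin e, with a median of 1841315. In the compared groups it was 1247211 to 9476215 in muscle, 508160 to 11119063 in skin, 1649459 to 2360216 in kidney, 1133476 to 3266825 in the eye parts, 2539663 to 3594862 in pectoral and pelvic fin, 438434 to 1155304 in tectum and torus, and 8084988 to 9456821 in larvae. Genes are given by symbol, cypCar identifier and position on the contigs of the deposited annotation, and levels as CPM (edgeR's cpm on TMM-scaled library sizes), mean ± SD over libraries. Lettered, numbered or sided libraries may be pieces of 1 animal, so every p-value measures only the spread between these samples. Intervals and floors cover counting error only. The groups, comparisons, gene lists and rule for naming genes were fixed before the data were examined.

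The tissues were compared to see which genes each expresses above the others, the purpose that the series description gives as RNA-seq of several carp tissues. The thymus led with rag1 (cypCar_00005756, Contig17469, 96449 to 100699), which cuts antigen receptor genes for rearrangement, at 4375 ± 681 CPM (n = 4) against 10.8 in kidney, the next highest tissue, and with the thymic protease PRSS16 at 102 ± 25.6 CPM. The male gonads led with Sycp1 (cypCar_00006234, Contig5582, 47399 to 54602), a protein of the meiotic synaptonemal complex, at 903 ± 37.2 CPM (n = 2) against at most 0.806 elsewhere. In the gallbladder samples the islet hormone gene ins (cypCar_00023606, Contig31222, 63897 to 65320) stood at 3008 ± 2093 CPM (n = 5) against 12.4 in brain. Heart was marked by the atrial light chain MYL7 at 13159 ± 4928 CPM (n = 2), gill by PAX1, a pouch patterning factor, at 26.6 ± 4.56 CPM (n = 6), barb by the taste receptor TAS1R3 at 27.9 ± 18.5 CPM (n = 2), and muscle by Ampd1 at 5263 ± 2722 CPM (n = 10). The fins were marked by hoxa11b (cypCar_00010163, Contig4375, 102032 to 104628), a factor of appendage patterning, at 29.5 ± 3.88 CPM (n = 7) against 2.55 in muscle.

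The marker lists were concentrated in particular organs. In brackets stand the camera adjusted p and then the adjusted p with an estimated correlation, or the latter alone. All 52 tested models of the testis germ cell list were enriched in gonads (4.9e-101 and 6.7e-22). All 57 lens models were enriched in eye (9.4e-52 and 0.038), as were 104 of 110 photoreceptor models (2.6e-137 and 7.8e-05). Fast muscle models were enriched in muscle in 52 of 57 cases (2.7e-55 and 0.000695), T cell models in thymus in 34 of 43 (5.8e-55 and 6.0e-07), cardiac models in heart in 42 of 73 (2.5e-63 and 4.2e-05) and neuron models in brain in 74 of 82 (5.2e-37 and 0.00594). In kidney 54 of 74 neutrophil and macrophage models (0.00123), 39 of 50 B cell models (0.00375) and 25 of 31 erythroid models (0.0144) were enriched, as were 69 of 106 tubule models, whose call was lost with an estimated correlation (adjusted p = 0.140). Gill held 21 of 48 ionocyte models (0.000267), and gallbladder 20 of 38 smooth muscle models (0.0157) and 23 of 42 exocrine pancreas models (0.00785). Epidermis and mucus models were enriched in barb (60 of 83), fin (57), tail (56), gill (55) and skin (54), each call holding with an estimated correlation. Proliferation models were enriched in gonads in 50 of 54 cases (0.0427). The brain label, which takes in the pituitary and optical nerve libraries, held 19 of 21 pituitary hormone models and 31 of 59 myelin and glia models, and both calls were lost with an estimated correlation (adjusted p = 0.405 and 0.0768). For these lists the counts adjusted over the list alone were the same except for cardiac muscle, with 45.

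Over 43566 genes and 89 libraries, 29008 genes were enriched in at least 1 of the 15 tissues tested by edgeR. Enriched meant an adjusted p under 0.05 and log2 fold of at least 2 over the mean log2 level of the other 18 tissues. As that mean is of log2 levels, a gene can be enriched in a tissue where it lies far below its highest tissue. MYL7 was enriched in gallbladder at 5.84 CPM, with 13159 CPM in heart. Brain had the most enriched models with 9990, then gonads with 8212 and eye with 7151, and hepatopancreas the fewest with 2827. Of these genes 9115 were enriched in 1 tissue, 7389 in a pair of tissues and 12504 in 3 or more. On a sample of 10000 genes the real grouping gave 6694 enriched genes. Random regroupings of the same libraries gave a median of 3266 and at most 3909, with calls in all 23. The counts alone therefore do not tell how many genes mark the labelled tissue. Fin and tail shared 3781 enriched genes against 507 expected were the calls of both tissues independent. Hepatopancreas and spleen shared 2325 against 216 expected. The overlap of hepatopancreas and spleen, and their counts of enriched genes, follow labels by which these libraries did not separate. Across genes, log CPM of hepatopancreas a correlated with spleen e at r of 0.915 and with hepatopancreas d at 0.563. Asking in addition for 5 times the highest other tissue left 4 genes in fin, 1 in tail, 1 in hepatopancreas and 4 in spleen, while 1476 stayed in gonads and 1789 in brain. In the 285 tests of lists in tissues, 162 were called with the preset correlation, of which 51 pointed up, and 29 with an estimated correlation, 133 of the former being lost.

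**Figure D1:**
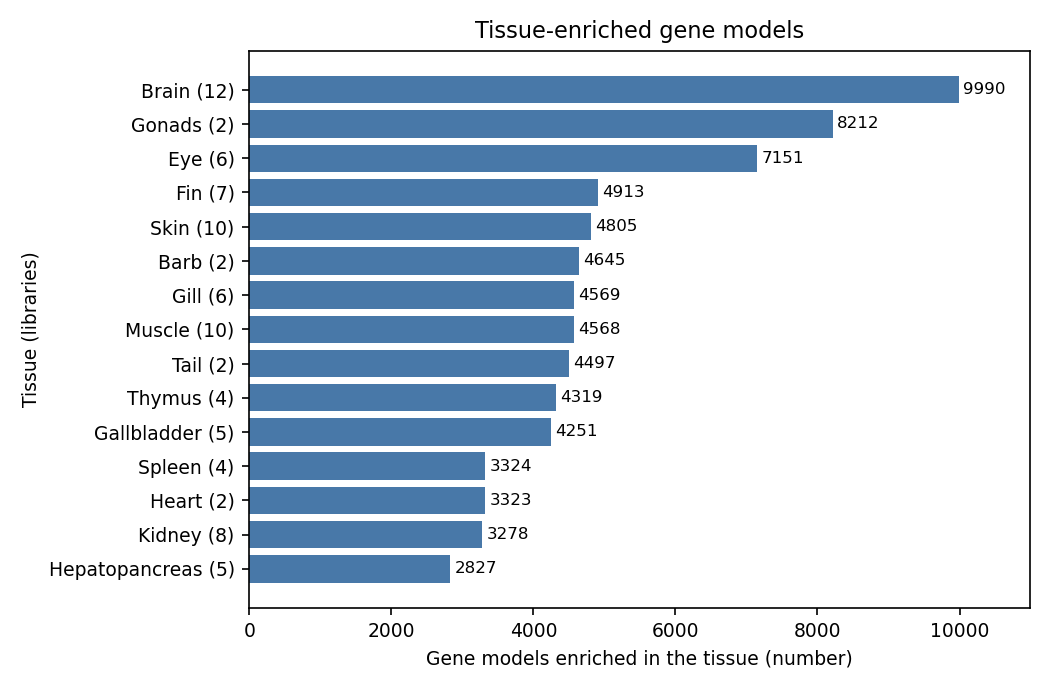
Number of gene models enriched in each of the 15 tested tissues (horizontal bars, with libraries per tissue in brackets). Enriched meant an adjusted p under 0.05 and a log2 fold of at least 2 over the mean log2 level of the other tissues. Brain has the longest bar with 9990 models and hepatopancreas the shortest with 2827. Random regroupings of the libraries gave enriched genes too. The hepatopancreas and spleen bars follow labels by which these libraries did not separate.

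Hepatopancreas and spleen libraries did not separate by label. Genes of the liver list, which make plasma proteins, held 14.7% of counts in hepatopancreas d (95% exact Clopper-Pearson interval 14.6 to 14.8) and 10.0% in hepatopancreas e (9.95 to 10.09), but 0.0676% (0.0610 to 0.0747), 0.0586% (0.0519 to 0.0660) and 0.0714% (0.0650 to 0.0783) in hepatopancreas a, b and c. In the spleen libraries a, b and d they held 14.5% (14.5 to 14.6), 9.28% (9.23 to 9.33) and 6.22% (6.16 to 6.29), and in spleen e 0.0445% (0.0429 to 0.0461). The erythroid list, mostly hemoglobin genes, ran the other way, with 16.0% (15.9 to 16.0) in spleen e and 8.41% (8.34 to 8.49), 14.7% (14.6 to 14.8) and 7.63% (7.56 to 7.70) in hepatopancreas a, b and c. Across genes, log CPM of spleen e correlated with hepatopancreas a, b and c at r of 0.915, 0.921 and 0.923, and hepatopancreas a with hepatopancreas d at 0.563; genes are not independent replicates. Of the 90 liver models, 83 were enriched in the spleen group (85 adjusted over the list alone; camera adjusted p = 1.4e-88, and 0.00533 with an estimated correlation). In the hepatopancreas group 83 of 90 were enriched as well (85 adjusted over the list alone; camera adjusted p = 1.7e-53), a call lost with an estimated correlation (adjusted p = 0.0624). Exocrine pancreas models, which encode digestive enzymes, were enriched in 23 of 42 cases in both groups (0.00515 in hepatopancreas and 0.00408 in spleen with an estimated correlation). Every value given for these groups follows the labels.

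**Figure D2:**
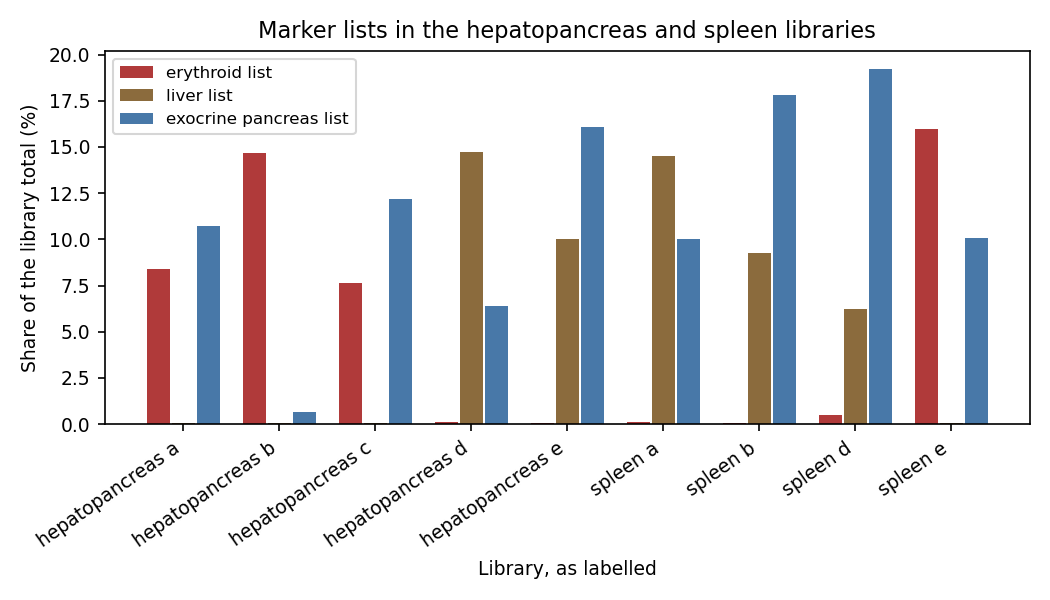
Percent of counts in genes of the erythroid, liver and exocrine pancreas lists (bars, axis from 0) for each hepatopancreas and spleen library. The liver share is above 6% in hepatopancreas d and e and spleen a, b and d, and the erythroid share above 7% in hepatopancreas a, b and c and spleen e.

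Dorsal and ventral muscle were compared to see how the musculature differs along the back to belly axis, 5 libraries against 5. In ventral muscle 33 of 45 slow muscle models were lower, in a list call that was lost with an estimated correlation (adjusted p = 0.169). Tnnt1 (cypCar_00015302, Contig16857, 46888 to 48615), slow troponin T, had 1.36 ± 0.757 CPM in ventral and 290.3 ± 285 in dorsal libraries (log2 fold -7.82, SE 0.816, adjusted p = 0.000493). TNNI1 (cypCar_00029174, Contig679, 46956 to 51548), slow troponin I, had 1 count over the ventral libraries against 80.7 ± 80.8 CPM in dorsal, a ratio of 1583 (counting interval 284 to 62553), and the oxygen store mb fell by 4.36 on the log2 scale. In ventral muscle mstnb (cypCar_00012017, Contig1682, 13708 to 16369), a myostatin that restrains muscle growth, was higher at 22.5 ± 8.70 against 2.77 ± 0.554 CPM (log2 fold 2.92, SE 0.285, adjusted p = 0.000403), as was the matrix gene Postn (cypCar_00033872, Contig26923, 10243 to 42229) at 305.5 ± 48.2 against 88.1 ± 14.0 CPM (1.79, SE 0.194).

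By list, no slow muscle model rose (41 lower and 1 higher adjusted over the list alone, median -3.70; camera adjusted p = 7.6e-23). Of 85 oxidative phosphorylation models, which encode the respiratory chain, 80 fell (83 adjusted over the list alone, median -1.27; 3.1e-38, and adjusted p = 0.169 with an estimated correlation), among them UQCRFS1 at -2.46 and Cox5a at -2.11. Of 55 extracellular matrix models 16 rose, including COL6A1 at 1.71 and LUM at 1.08, and TNC fell by 1.04 (22 higher and 3 lower adjusted over the list alone; camera adjusted p = 7.5e-09, and 0.201 with an estimated correlation). Of 50 fast muscle models 18 fell, MYBPC2 by 5.41 and a TNNI2 model by 7.23, and ACTN3 rose by 1.43 (22 lower and 4 higher adjusted over the list alone). The fast list median was 0.26 while its test pointed down without a call (adjusted p = 0.275). Of 4 limb position models TBX18 rose by 2.34 and 3 fell, a pitx3 model by 2.35 (the same counts adjusted over the list alone; camera adjusted p = 0.0476, and 0.169 with an estimated correlation). CTSK, a bone resorption protease, rose by 0.71 in the bone and scale list of 7 (4 higher adjusted over the list alone; camera adjusted p = 0.0117, and 0.169 with an estimated correlation). In the heat shock list 4 of 41 fell, HSPB1 by 2.66, and 3 rose, fos by 1.17, and 2 of 8 iridophore and xanthophore models fell, Bco2 by 4.15; the counts were the same adjusted over the list alone and neither list was called (adjusted p = 0.275 for both). Pkp3 fell by 1.00 in an epidermis list of 30 that was not called (adjusted p = 0.693, median 0.25 with the test down; 0 adjusted over the list alone), and none of 5 erythroid models passed (adjusted p = 0.721, median -0.08 with the test up).

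Of 9301 genes tested by edgeR, 304 were higher and 1041 lower in ventral muscle. Slow muscle genes held 3.94 ± 3.40% of dorsal and 0.480 ± 0.320% of ventral counts, and the fast list 27.1 ± 5.08% and 34.1 ± 2.46%. Without dorsal d the count was 2078, and with no filter on low counts 2490.

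**Figure D3:**
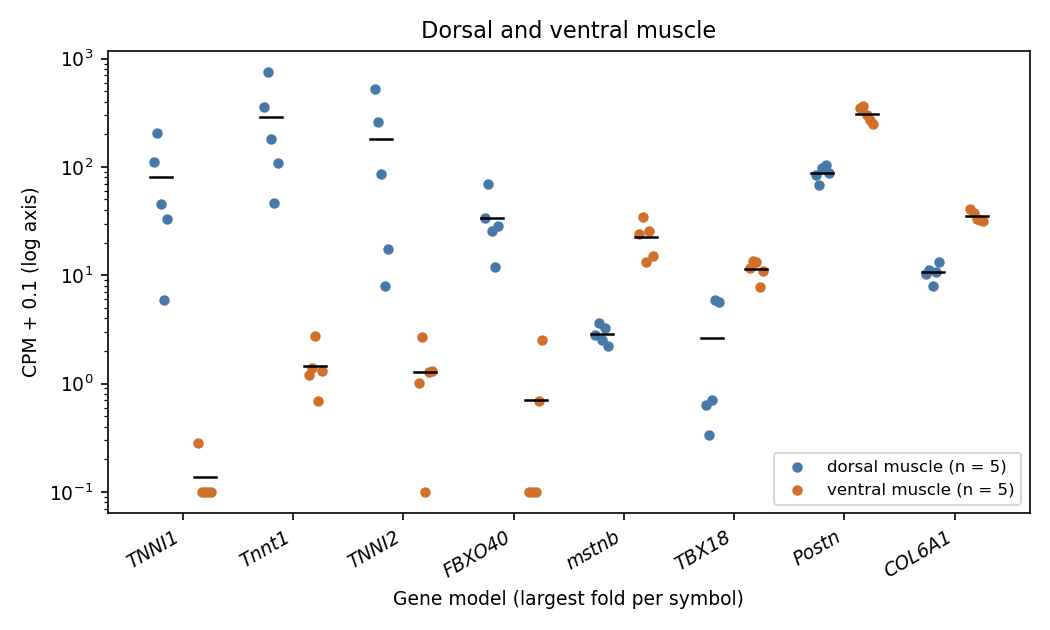
CPM plus 0.1 on a log axis for 8 genes in dorsal and ventral muscle (points, 5 libraries per group; lines, means). TNNI1, Tnnt1, TNNI2 and FBXO40 lie lower in every ventral library, and mstnb, TBX18, Postn and COL6A1 higher.

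Dorsal and ventral skin were compared in the same way, 5 libraries against 5. In ventral skin 18 of 41 fast muscle models were higher, in a list call that was lost with an estimated correlation (adjusted p = 0.271). The calcium pump gene atp2a1 (cypCar_00006488, Contig2333, 100447 to 107882) had 2793 ± 918 CPM in ventral and 194 ± 331 in dorsal skin (log2 fold 3.84, SE 0.864, adjusted p = 0.0376), and a TNNI2 model 87.6 ± 44.8 against 5.06 ± 9.23 CPM. Lower in ventral skin were 2 genes of cytoskeletal linker proteins, Plec (cypCar_00025996, Contig21434, 1327 to 3688) at 1.60 ± 2.06 against 12.4 ± 3.17 CPM (log2 fold -2.28, SE 0.394, adjusted p = 0.0112) and Eppk1 (cypCar_00002018, Contig14252, 52360 to 57450) at 11.2 ± 7.96 against 56.0 ± 16.9 CPM (-1.93, SE 0.309, adjusted p = 0.00735). The fast muscle list held 1.88 ± 0.419% of counts in ventral and 0.570 ± 0.478% in dorsal skin, so muscle RNA moved with the group.

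In the fast muscle list none fell (27 higher adjusted over the list alone, median 2.17; camera adjusted p = 5.8e-14, and 0.271 with an estimated correlation). The slow muscle list of 39 pointed down (median -1.52; 6.7e-09, and adjusted p = 0.390 with an estimated correlation), and its only called member, MYH7, rose by 3.52, also adjusted over the list alone. Of 71 extracellular matrix models 16 rose, Postn by 1.46 and DCN by 0.80 (31 higher and 1 lower adjusted over the list alone; 9.4e-10, and adjusted p = 0.390 with an estimated correlation), as did SPARC by 0.61 in the bone and scale list of 13 (2 higher, or 4 higher and 2 lower adjusted over the list alone; adjusted p = 0.765). Of 8 erythroid models 3 rose, hbb by 2.25 (4 adjusted over the list alone; camera adjusted p = 0.000672, and 0.133 with an estimated correlation). The melanophore list of 12 pointed down with no member called over all genes (0.0015, and 0.133 with an estimated correlation), while tyr at -0.79 and tyrp1 at -1.10 were among 4 lower models adjusted over the list alone. DSP, a desmosome linker, had all 3 called members of the 64 epidermis models, the strongest at -1.08 (11 lower and 5 higher adjusted over the list alone; adjusted p = 0.0612). MMP9 rose by 0.74 among 35 neutrophil and macrophage models (2 higher adjusted over the list alone; adjusted p = 0.172) and Nlrc5 fell by 0.66 among 84 interferon models (1 adjusted over the list alone; adjusted p = 0.936, median -0.05 with the test up). No B cell, T cell, iridophore and xanthophore or limb position model passed over all genes or adjusted over the list alone (adjusted p = 0.936, 0.286, 0.936 and 0.224). The mean of the B cell and of the bone and scale list was below 0 while median and test pointed up.

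Of 21411 genes tested by edgeR, 300 were higher and 139 lower in ventral skin. The count was 166 without dorsal c, 203 without dorsal d, 265 without dorsal e, 282 without ventral a and 203 without ventral b, 240 at a log2 fold of at least 1, and 2 in a fit to all 93 libraries. The dorsal to ventral difference itself differed between muscle and skin for 1493 of 22620 genes, 1317 of them with a higher ventral to dorsal fold in skin; the fast muscle gene Mybpc2 (cypCar_00008924) had -4.84 in muscle and 2.17 in skin, where the share of fast muscle RNA was higher in ventral libraries. Of 8376 genes tested in both, 33 were called in both and 23 of these had the same sign. In both ventral tissues 21 were higher against 7.64 expected and 2 lower against 3.77 expected, were the calls of both tissues independent. The former include the matrix gene FN1 (1.04 in muscle, 0.94 in skin).

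Head and mid kidney were compared to see how the anterior, blood-forming kidney differs from the excretory part, 4 libraries against 4. In mid kidney 49 of 56 tubule models were higher, in a list call that was lost with an estimated correlation (adjusted p = 0.0919). LRP2 (cypCar_00031434, Contig2264, 329 to 54072), the protein uptake receptor megalin, had 340 ± 194 CPM in mid and no count in head kidney (at least 802-fold), and Slc13a1 (Contig2013, 50505 to 57345), a sulfate transporter, 1244 ± 320 CPM against 1 count (ratio 8892, counting interval 1596 to 351246). In head kidney 10 of 15 models of the interrenal and chromaffin list, named for the fish counterpart of the adrenal gland, were higher (adjusted p = 0.316 with an estimated correlation). CYP21A2 (cypCar_00007548, Contig2834, 93835 to 101821) had 147 ± 139 CPM there and none in mid kidney (at least 359-fold lower), and star (cypCar_00007608, Contig5437, 152136 to 155066), which moves cholesterol into mitochondria, 426 ± 345 against 0.615 ± 0.852 CPM (log2 fold -9.43, SE 0.948, adjusted p = 4.9e-07).

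Of the tubule models SPINK2 alone fell, by 0.56 (52 higher and 1 lower adjusted over the list alone). The tubule median was 8.84 as fitted and 7.27 with the 17 models at 0 in a group set at their bound (camera adjusted p = 7.3e-39, and 0.0919 with an estimated correlation). Of the interrenal and chromaffin models 3 rose in mid kidney, DDC by 6.36 (11 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.00254, and 0.316 with an estimated correlation). Of 53 neutrophil and macrophage models 36 fell, CXCR1 by 3.02 and MMP9 by 2.47, and 3 rose, a pair of MFAP4 models and MARCO (39 lower and 3 higher adjusted over the list alone; camera adjusted p = 1.2e-10, and 0.0919 with an estimated correlation). Of 27 erythroid models 18 fell, slc4a1 by 2.09, and 2 rose (19 and 3 adjusted over the list alone; camera adjusted p = 1.0e-05, and 0.233 with an estimated correlation). Of 35 B cell models 19 fell, CD22 by 1.49, and 3 rose, BLNK by 4.79 (21 and 3 adjusted over the list alone; camera adjusted p = 0.000227, and 0.120 with an estimated correlation). Of 18 T cell models 12 fell, Ccr9 by 1.53, and rag2 rose by 0.69 (13 and 1 adjusted over the list alone; camera adjusted p = 0.000635, and 0.173 with an estimated correlation). Podocyte and proliferation lists were not called (adjusted p = 0.0801 and 0.132), although Podxl rose by 3.17 among 3 higher and 1 lower of 9 podocyte models, and KIF23 by 1.35 among 4 higher and 1 lower of 50 proliferation models, with the same counts adjusted over the list alone.

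Of 17419 genes tested by edgeR, 2954 were higher and 2538 lower in mid kidney. The erythroid list held 8.43 ± 0.511% of head and 4.09 ± 2.01% of mid kidney counts. The count was 8575 with no filter on low counts, 3153 in a fit to all 93 libraries and 2825 at a log2 fold of at least 1.

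**Figure D4:**
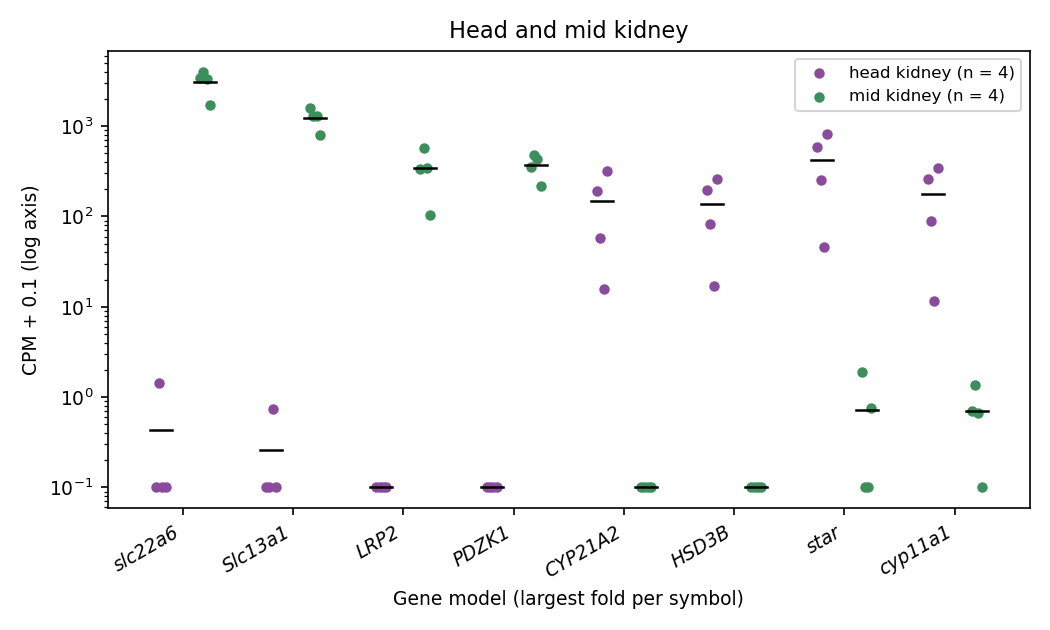
CPM plus 0.1 on a log axis for 8 genes in head and mid kidney (points, 4 libraries per group; lines, means). The tubule genes slc22a6, Slc13a1, LRP2 and PDZK1 lie higher in every mid kidney library, and the interrenal genes CYP21A2, HSD3B, star and cyp11a1 in every head kidney library.

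Eye front and eye rear were compared to see how the front and rear of the eye differ, 2 libraries each, with both crystalline libraries in the fit. The labels do not say how the eyes were divided, and the genes below leave open whether front and rear mean what the words say. Of 61 epidermis models 16 were higher in the libraries labelled rear. Tp63 (cypCar_00004814, Contig19861, 86139 to 94126), a regulator of stratified epithelia, had 10.7 ± 0.0424 CPM in rear and no count in front libraries (at least 16.3-fold, adjusted p = 0.0307). Of 35 myelin and glia models 3 were higher in the libraries labelled front, among them mbp (cypCar_00024276, Contig8735, 3787 to 14337) at 5241 ± 3644 against 12.3 ± 10.3 CPM (log2 fold -8.71, SE 1.04, adjusted p = 0.0280) and gfap, a glial filament, at -3.99. In the epidermis list Cldn1 rose by 5.47 and PKP1 by 4.37 in rear (37 higher and 3 lower adjusted over the list alone; camera adjusted p = 8.0e-13, and 0.113 with an estimated correlation). The myelin and glia list pointed down in rear (13 lower and 3 higher adjusted over the list alone; camera adjusted p = 3.0e-05, and 0.435 with an estimated correlation). Rab38 alone fell, by 5.05, among 39 pigment models (2 lower adjusted over the list alone; camera adjusted p = 0.00013, and 0.437 with an estimated correlation), and NEFL alone, by 4.22, among 28 neuron models (1 lower and 3 higher adjusted over the list alone, median 0.77; camera adjusted p = 0.0127, and 0.437 with an estimated correlation).

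No photoreceptor, lens, erythroid, extracellular matrix or oxidative phosphorylation model passed over all genes between the eye parts, and of these only extracellular matrix had members adjusted over the list alone (6 higher, 1 lower). The photoreceptor median was 0.54 (camera adjusted p = 3.9e-05, and 0.476 with an estimated correlation), the matrix median 0.84, or 0.81 at bounds (3.0e-05; 0.113), the erythroid median -1.46 (0.000424; 0.437) and the lens median -0.59, or -0.52 at bounds (0.00292; 0.435). Oxidative phosphorylation was not called (adjusted p = 0.479). The fast muscle share was 7.28% in rear left (exact interval 7.25 to 7.31) and 0.0971% in rear right (0.0927 to 0.102), and the erythroid share 8.55% in front right (8.50 to 8.60) and 1.15% in front left (1.13 to 1.16). Of 23463 genes tested by edgeR 183 were higher and 157 lower in eye rear. The count was 0 without front left, 193 without rear left, 105 without front right and 1083 without rear right, 0 when only the compared libraries were fitted, 1390 with the sides as a replicate block, 2714 with no filter and 759 by DESeq2. The test on simulated data at this size found 54.5% of genes changed by a log2 fold of 3 and 7.46% at 2.

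The crystalline was set against the mean of eye front and rear to see which genes mark the lens. Crystallins, the refractive proteins of lens fibres, were far higher. Crybb1 (cypCar_00006461, Contig4274, 38573 to 40894) had 49368 ± 5604 CPM against 12 counts over the 4 other libraries (log2 fold 15.47, SE 0.570, adjusted p = 1.1e-06) and cryaa (cypCar_00020148, Contig4728, 69724 to 74507) 10020 ± 1016 against 0.618 ± 0.872. Of 56 lens models 55 rose, also adjusted over the list alone (median 13.84 as fitted and 13.66 at bounds; camera adjusted p = 1.5e-55, and 0.00652 with an estimated correlation). Of 104 photoreceptor models 76 fell, GUCA1A (Contig57989, 25176 to 29082), a calcium sensor of light response, from 77.8 ± 16.5 CPM to no count (at least 54.5-fold lower). A pair of NRL models and the GNB3 model cypCar_00031879 rose. The more abundant GNB3 models were lower in crystalline. On the scale of the tissue fit, cypCar_00035445 had 0.575 CPM there against 229 in front and 300 in rear. The model cypCar_00016629 had 0.541 CPM against 75.2 and 97.5. Adjusted over the photoreceptor list alone, 81 models were lower and 3 higher. The list median was -5.48 as fitted and -3.72 at bounds (camera adjusted p = 7.3e-18, and 0.161 with an estimated correlation). Lens genes held 33.7 ± 2.83% of crystalline counts. Of 23463 genes tested by edgeR 2935 were higher and 3969 lower, and the count was 1926 without crystalline left and 1708 without crystalline right.

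Pectoral and pelvic fin, the paired fins that correspond to fore and hind limb, were compared with 2 libraries each, the other fins sharing the fit. Limb identity factors differed in both directions. Tbx4 (cypCar_00008414, Contig2596, 13660 to 27073), the hind limb T-box factor, had 35.7 ± 17.9 CPM in pelvic fin against 1 count in pectoral fin (ratio 199, counting interval 35.3 to 7875; adjusted p = 0.00604). PITX1 (cypCar_00026525, Contig7554, 45592 to 49217), its upstream hind limb factor, had 29.8 ± 3.47 against 2.18 ± 0.239 CPM (log2 fold 3.76, SE 0.411). The forelimb factor tbx5a (cypCar_00024156, Contig3524, 27459 to 39010) had 11.6 ± 1.79 CPM in pectoral and no count in pelvic fin (at least 27.7-fold lower, adjusted p = 0.0401). Crystallins were lower in pelvic fin too, CRYBB1 at 0.697 ± 0.587 against 14.9 ± 8.26 CPM (log2 fold -4.32, SE 0.624) and crygs by 3.49, while Lgmn and Tecta rose.

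Of 51 limb position models 2 rose and 2 fell (8 and 2 adjusted over the list alone, the former including hoxa9a at 1.76, median 0.03; adjusted p = 0.549). The 87 extracellular matrix models pointed down with none called over all genes (1 higher adjusted over the list alone; camera adjusted p = 0.00165, and 0.966 with an estimated correlation). No member passed over all genes in the erythroid (13 models; adjusted p = 0.763, median -0.06 with the test up), neutrophil and macrophage (49; 0.711), pigment (25; 0.749), iridophore and xanthophore (36; 0.763), epidermis (70; 0.978), bone and scale (43; 0.759) or proliferation lists (52; 0.749). The mean of the epidermis and of the bone list was above 0 while median and test pointed down. Adjusted over the list alone, 3 bglap models of the bone list were higher, Mpo at 2.40 and an MPEG1 model of the neutrophil and macrophage list, and 1 erythroid model. Of 29737 genes tested by edgeR 5 were higher and 15 lower in pelvic fin. The count was 0 without pectoral left, 0 without pectoral right, 3 without pelvic left and 66 without pelvic right, 48 with the sides as a replicate block, 146 with no filter and 57 by DESeq2.

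**Figure D5:**
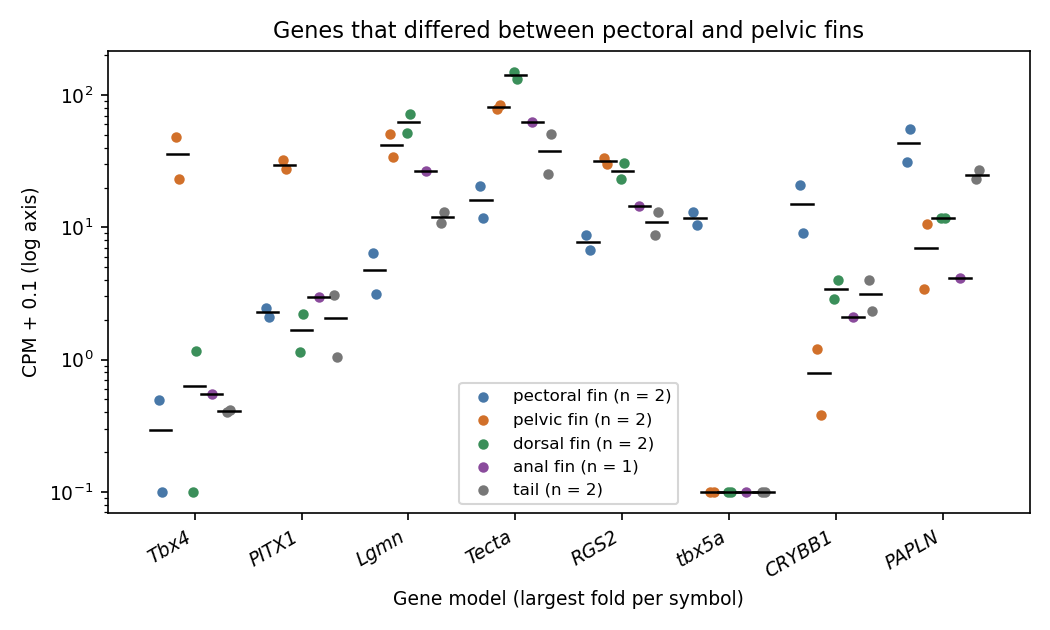
CPM plus 0.1 on a log axis for 8 genes in pectoral, pelvic, dorsal and anal fin and tail (points, libraries; lines, means). Tbx4 and PITX1 average 35.7 and 29.8 CPM in pelvic fin and are lower in pectoral fin. In pectoral fin tbx5a and CRYBB1 are higher than in pelvic fin.

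Tectum opticum, the visual midbrain roof, and torus semicircularis, the auditory midbrain below it, were compared with 2 libraries each. No gene of 15771 passed by edgeR; 536 had an unadjusted p under 0.05 and DESeq2 called 0. Glutamate neuron models pointed up in torus (54 models, median 1.15, camera adjusted p = 0.000635), as did neuron models (55, 0.63, 0.00164), while oxidative phosphorylation models (91, median -0.78, 2.0e-16) and erythroid models (12, -1.26, 0.00113) pointed down. All were lost with an estimated correlation (adjusted p = 0.509, 0.509, 0.509 and 0.467). The GABA and glycine list of 30 (median -0.42, test up, adjusted p = 0.984), the myelin and glia list of 30 (median -0.45, 0.0953) and a pair of photoreceptor models (0.496) were not called, and none of these lists had a member adjusted over the list alone. Without torus left 2 genes were called, with a replicate block of the sides 24, with no filter 13 and in a fit to all 93 libraries 92. On simulated data at this size the test found 0% of genes changed by a log2 fold of 3.

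Larvae labelled infected and larvae labelled control were compared with 2 libraries each to see what infection changes; the labels do not name the agent, and the letters in the deposited names run against the titles, which were followed. Both libraries numbered 1 were rich in muscle and both numbered 2 in blood cells, whatever the label. The skeletal actin acta1 (cypCar_00048243) stood at 12852 CPM in labelled control 1 and 12752 in labelled infected 1, and at 0.912 and 15.7 in the libraries numbered 2. The hemoglobin gene hba (cypCar_00042298) stood at 0.208 and 0.742 CPM in those numbered 1, and at 28116 and 49604 in those numbered 2. No gene of 38949 passed by edgeR, 0 had an unadjusted p under 0.05 and DESeq2 called 0, while a replicate block of the numbers gave 11, all lower. On simulated data at this size the test found 0% of genes changed by a log2 fold of 3. Neither the test nor the simulation had a term for the difference between libraries numbered 1 and 2, which entered both as spread. No list test was run with the replicate block either, so a list without a call does not speak against a response to infection. The interferon list of 125 (median -0.08, test up, adjusted p = 0.565) and the inflammation list of 82 (0.975, median 0.25, mean -0.03) were not called, nor were fast muscle (0.209, median -0.12, test up), neuron (0.0817), neutrophil and macrophage (0.707) and proliferation (0.0785). Liver (76 models, median 0.36, camera adjusted p = 0.000554), exocrine pancreas (23, 0.42, 6.9e-05) and erythroid models (38, 0.58, 0.00257) pointed up, and oxidative phosphorylation (95, -0.29, 6.8e-15) and heat shock models (71, -0.30, 0.000688) down. These calls were lost with an estimated correlation (adjusted p = 0.988 for liver and 0.920 for the others), and no list had a member adjusted over the list alone.

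Left and right were compared over 15 pairs to see whether the sides of paired organs differ. No gene of 19717 passed by edgeR; 1470 had an unadjusted p under 0.05, DESeq2 called 0 and dropping the low count filter gave 54. The test found 97.0% of genes changed by a log2 fold of 1 on simulated data. Each simulated gene had the same mean level in all organs, and only well-expressed genes were changed. Power for real genes, whose levels differ between organs, may be lower. Neutrophil and macrophage models pointed to the right side (36 models, median 0.21, camera adjusted p = 4.9e-06), as did interferon (76, 0.11, 1.0e-04) and inflammation models (55, 0.12, 0.00478), and fast muscle models to the left (17, -0.70, 0.0183). These calls were lost with an estimated correlation (adjusted p = 0.561 for the immune lists and 0.790 for fast muscle). Adjusted over the list alone only Rab27a of the pigment list passed, at 0.46 (list adjusted p = 0.43). Extracellular matrix (0.391), erythroid (0.701), T cell (0.781), epidermis (0.781) and heat shock (0.701) were not called.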

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

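The test of infection for the larvae and the test of lens RNA spread alike over all libraries were chosen after the results were seen; the other tests of this part were written down beforehand. Dixon's test was applied to the share of counts of 6 marker lists in 66 combinations of list and group, and 12 had a library far from the others, where chance alone gives about 1 in 20.

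The hepatopancreas and spleen libraries carried each other's marker genes, as the liver and erythroid shares of the report show. Spleen e stood apart from spleen a, b and d in 4 lists, with 16.0% erythroid counts (exact 95% interval 15.9 to 16.0; others 0.0781 to 0.484), 0.0147% fast muscle (0.0138 to 0.0157; others 0.00173 to 0.00305), 0.163% epidermis and mucus (0.160 to 0.166; others 0.0518 to 0.0538) and 0.00906% neuron counts (0.00835 to 0.00982; others 0.00215 to 0.00310). The lowest neutrophil and macrophage share of hepatopancreas a, b and c was 2.83 times the highest of spleen a, b and d, the order that exchanged labels would give, so an exchange of labels is a candidate explanation. Liver tissue mixed into the spleen samples cannot be told apart from it by the remaining test, since the highest B cell share of spleen a, b and d was 0.179 times the lowest of hepatopancreas a, b and c and spleen e, between the bounds set for and against mixing, though mixing gives no account of the low liver share of hepatopancreas a, b and c. No biological explanation was tested, as the design gives none.

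Both larvae libraries numbered 2 resembled head kidney, with r of 0.92 to 0.95 across genes (genes are not independent replicates), although they are titled whole larvae. Infection as the cause was argued against, since the fast muscle share of the library labelled control 2 was 0.000784 times that of labelled control 1. The highest lens share of the libraries numbered 2 was 0.0910 times the lowest of those numbered 1, just under the bound of 0.1 set for samples without whole larvae, so these libraries may hold another sample than whole larvae. The age of the animals was not tested and stays open.

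Crystallins were higher in pectoral than in pelvic fin, where lens genes held 0.0487% (exact 95% interval 0.0461 to 0.0515) and 0.0256% (0.0239 to 0.0274) of pectoral counts against 0.00534% (0.00461 to 0.00615) and 0.00488% (0.00418 to 0.00568). Over the 55 lens models the log CPM of pectoral fin and crystalline correlated at r = 0.900 (across genes, which are not independent replicates). Lens RNA carried over into the pectoral fin samples would give such a correlation. Lens RNA spread alike over all libraries, or crystallin expression by the fin, could give it too. The correlation therefore does not choose between them. The test of lens RNA spread alike over all libraries did not decide. The lower pectoral share was 3.99 times the median of libraries outside the eye and larvae, between the bounds of 2 and 5 set for and against it. An even spread would, however, give pectoral and pelvic fin like shares. The pectoral shares of 0.0487% and 0.0256% against pelvic shares of 0.00534% and 0.00488%, with intervals that do not overlap, argue against it for these fins. Some libraries outside the eye had more than pectoral fin. Among them were 0.206% in ventricle (0.198 to 0.213), 0.123% in dorsal muscle b (0.121 to 0.125) and 0.113% in medulla oblongata (0.107 to 0.120). The list also holds models of CRYAB, a small heat shock protein. CRYAB cypCar_00028309 stood at 1281 ± 1103 CPM in heart (n = 2) and 65.5 ± 66.0 in muscle (n = 10). A different CRYAB model, cypCar_00042632, stood at 603 ± 648 CPM in muscle. Expression of crystallins by pectoral fin was not tested and stays open.

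The dorsal to ventral fold differed between muscle and skin for 1493 genes by the interaction test, beside a fast muscle share of 1.88 ± 0.419% in ventral and 0.570 ± 0.478% in dorsal skin (n = 5 each). The left library of gill arch 3 had 4.13% erythroid counts (exact 95% interval 4.10 to 4.16; others 0.424 to 1.15). Gallbladder 2 had 0.752% erythroid counts (0.745 to 0.758; others 0.0315 to 0.162) and gallbladder 1 0.289% liver counts (0.284 to 0.295; others 0.0694 to 0.127). The dorsal right head kidney library had 0.0736% fast muscle counts (0.0696 to 0.0777; others 0.00569 to 0.0101). Dorsal skin c had 0.0165% erythroid counts (0.0147 to 0.0184; others 0.0231 to 0.0255) and dorsal skin a 5.01% epidermis and mucus counts (4.98 to 5.04; others 4.33 to 4.45). Dorsal muscle c had 0.00312% exocrine pancreas counts (0.00235 to 0.00405; others 0.00102 to 0.00154) and dorsal muscle b 0.00611% liver counts (0.00562 to 0.00663; others 0.00302 to 0.00363). In the optical nerve library, which no comparison of pairs used, 82.3% of reads lay outside gene models (82.2 to 82.4), against 61.4% in the next library and a median of 37.6% in the others.

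Among the groupings drawn from the same libraries, only the real one gave so many genes. Muscle had 1345 genes (1 of 100 groupings as large, highest other 944) and skin 439 (1 of 100, highest other 170). Kidney had 5492 (1 of 35, highest other 0) and tissue-enriched genes 6694 of a sample of 10000 (1 of 24, highest other 3909). For the tissues 23 other groupings made calls too, with a median of 3266, and the cause was not tested. Chance in how the labels fell on these libraries is an unlikely source of the full counts. As libraries may be pieces of 1 animal, differences between animals were not tested. For left and right the regroupings decide nothing, because with 0 genes found all 60 of 60 groupings must give as many; the highest other was 2.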

How the results depend on the processing

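Only the fit without hepatopancreas, spleen and optical nerve libraries was chosen after seeing the data, and it moved no count of tissue-enriched genes by over 1.5 times. RLE factors moved no count either. No gene named between groups turned its direction under the alternatives run. For lists the only alternative run was an estimated correlation. It changes only the variance of the test, so it cannot turn a list's direction. Genes named in tissues and lists tested in tissues were not among the values compared. Of these 7848 values, 6808 kept their side of the threshold and 1040 lost the call; named genes had all been called, so none could gain a call, and the counts given next show where alternatives called more genes. The crystalline count has no separate fit to the compared libraries, since that fit is the main analysis. Where a lone library remained after another was left out, it was assumed to vary like the other groups. Depth was lowest in the optical nerve, with 233640 counts. Except for the filters and folds, which change the number of genes by their construction, the cause was not tested.

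Asking for 5 times the highest other tissue left 22 genes in barb, 1789 in brain, 491 in eye, 4 in fin, 117 in gallbladder, 142 in gill, 1476 in gonads, 169 in heart, 1 in hepatopancreas, 160 in kidney, 632 in muscle, 10 in skin, 4 in spleen, 1 in tail and 287 in thymus. A log2 fold of at least 1 gave 11200 in eye, 9990 in fin, 7164 in gallbladder, 8650 in gill, 12805 in gonads, 6559 in kidney, 8302 in muscle, 10396 in skin, 5251 in spleen and 9169 in thymus, and 240 between the skins and 2825 between the kidneys. DESeq2 gave 4560 in eye and 2707 in gallbladder, 759 between eye front and rear and 57 between the paired fins. No filter gave 2490 for muscle, 8575 for kidney, 2714 for eye front and rear, 146 for the paired fins, 13 for tectum and torus and 54 for left and right. Across genes, libraries with the same number or side deviated together at r of 0.95 in larvae and 0.51 in tectum and torus. In eye front and rear r was 0.29 and in the fins 0.17. Each of these values stands for only 2 pairs, which give the same r by construction. The mean r was -0.03 in muscle, 0.15 in skin and 0.01 in kidney. The replicate block gave 1390 for eye front and rear, 48 for the fins, 24 for tectum and torus and 11 for larvae. The fit to all 93 libraries gave 2 for skin, 3153 for kidney and 92 for tectum and torus, and that to the compared libraries only 0 for eye front and rear. Leaving out each library in turn gave 981 to 2078 for muscle, 166 to 582 for skin, 0 to 1083 for eye front and rear, 1708 to 6324 for crystalline, 0 to 66 for the fins and 0 to 2 for tectum and torus.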

Other observations

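The test of changed dominance between gene copies was written down beforehand; the levels of this part were chosen by the lists and the rule for named genes.

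The atrium, ventricle and bulbus, 1 library each, differed in their contractile genes. Models with the heart myosin symbols MYH7 and Myh6 went both ways. MYH7 cypCar_00021124 stood at 90448 CPM in ventricle against 25.4 in atrium, but Myh7 cypCar_00013130 at 824 in atrium against 602 in ventricle. Myh6 cypCar_00042708 stood at 7163 CPM in atrium against 3.36 in ventricle, but MYH6 cypCar_00013129 at 19.8 in atrium against 1593 in ventricle. The natriuretic peptide genes nppa and nppb stood higher in atrium, at 19176 against 7272 CPM and 1353 against 42.0 CPM. In the bulbus the smooth muscle genes Acta2 and MYH11 stood at 2215 and 1635 CPM, with the transcription factor hand2 at 641. Pituitary hormone genes held 22.3% of pituitary counts (exact 95% interval 22.3 to 22.4), led by gh at 90553 and pomcb at 84976 CPM. The optical nerve library held 1.92% (1.87 to 1.98) in the same list, with gh at 5520 CPM, and 6.91% (6.81 to 7.01) in exocrine pancreas genes.

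Position and region genes of single or paired libraries differed between regions. The posterior factor hoxc13a (cypCar_00025543) stood at 58.7 ± 5.18 CPM in tail (n = 2) and at 0 in the fins. The level of hoxc12a was 16.0 CPM in anal fin, 16.2 in tail and 4.99 ± 7.05 in dorsal fin (n = 2). In the brain, the glycine transporter slc6a5 stood at 29.1 CPM in vagal lobe and 25.1 in medulla oblongata and at 0 in telencephalon. The telencephalon held the neuronal transcription factors neurod6a at 83.4 and dlx2a at 21.4 CPM. Gut held EVX1 at 96.3 CPM and swim bladder Fbp2 at 12917. The library titled PBL, with the tissue label blood, held the coagulation gene F13a1 at 1147 CPM and the platelet receptor gene GP1BA at 315. Exocrine pancreas genes held 9.64% of gut counts (9.57 to 9.71), and 22.0 ± 9.84% in gallbladder (n = 5).

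Carp carries many genes as paired copies, and of 5837 symbols with 2 gene models 4660 were measured in at least 2 tissues. In 3053 of them 1 model led by a log2 of at least 1 in every library of some tissue, and for 192 (4.12%) the leading model changed between tissues. Chance in how the labels fell on these libraries is an unlikely source, since 1 of 100 groupings gave as many and the highest other was 36. For MBL2, a lectin of innate immunity, 1 model stood at 58.4 ± 41.2 CPM in gill against 0.711 for the other, and at 0.640 in kidney against 927 ± 551. The copies may be used by different tissues, although a symbol shared by unlike products, as for HSPB11, gives the same picture, and the 192 were not screened for it.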
